A study of Homo sapiens with 4 samples.

How the data were processed

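RNA was sequenced from MCF10AT cells in 4 libraries, 2 labelled Bromo+/- and 2 labelled non-target control. Per the labels' protocols, the cells were grown with horse serum, epidermal growth factor, insulin, cholera toxin and hydrocortisone, RNA was extracted with Trizol, and libraries were made with a stranded poly(A) mRNA kit. The labels' protocols also describe lentiviral shRNA transduction with puromycin selection, while the genotype of these 4 samples says only Bromo+/- or non-target control.

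The authors deposited raw read counts per Ensembl gene, not normalized, in one table. Per the submitters' processing notes, reads were aligned with STAR (version not given) to GRCh38 and counted with featureCounts 1.5.2. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies may therefore be split or shared. Some such genes are marked as uncertain where named, but not all: exons of CLDN7, BRD3, RNF43, LOXL2, TYMS and BICDL2, among others, overlap those of another gene with counts. Columns were matched to samples by name. The control columns carry a name with WT, matched to the non-target control because the other columns abbreviate Bromo and WT names the unaltered counterpart of a +/- genotype. Within each group the column names also share a number besides the replicate number, and its meaning is not given. No column of per-sample values was left over. Of the 58233 gene identifiers, 57392 were named from a table of current symbols and 503 from GENCODE v29, and 338 had no name. Coordinates are those of the deposited table, from the first to the last exon base.

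Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (13179 genes), library sizes were scaled by the trimmed mean of M values (factors of 1.03 and 1.03 for the libraries labelled Bromo+/-, 0.968 and 0.975 for the controls), and groups were compared with the robust quasi-likelihood test with 2 residual degrees of freedom and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. The standard error of a log2 fold change comes from the fitted model. The common biological coefficient of variation was 3.52%. The replicate number was not used as a block, since no label says that it marks anything shared. A gene without counts in a group is given as a bound against 3 counts over the group, and a gene with 1 to 3 counts in a group as a ratio with its 95% exact binomial interval.

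Replicates were compared before they were averaged. Pearson's r of log2 CPM, across genes, was 0.995 within each group and 0.912 at most between groups. A chi-square statistic over genes with at least 10 counts was 2.44 per degree of freedom within the group labelled Bromo+/- and 1.56 within the controls, more than sampling noise alone gives, so no library was counted as a copy of another. Totals of 10835237 to 11975396 counts put 3 counts at 0.251 to 0.277 CPM per library.

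Gene lists (43 lists with 1050 entries, 1048 found in the table) were written before the data were examined, from textbook knowledge of the cell line, of p300 and of epithelial, mesenchymal, growth, stress and metabolic programmes, with markers of other cell types and of RNA quality. Each list with at least 5 tested members was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. The genes named in the text are EP300 and CREBBP, then, among genes past the threshold with an average log2 CPM of at least 2 and both libraries of a group on the same side, the 10 with the largest rise and the 10 with the largest fall, the 5 higher and 5 lower with the smallest p, and from each list that passed camera or had at least 3 members past the threshold up to 4 members with the smallest adjusted p. Members named because a count of 5 or fewer is spelled out, and the genes and families of the closing section, were chosen after their values were seen. Some genes met by these rules are withheld and are not reported here.

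The procedure was checked on simulated counts drawn from the means, library sizes and spread of these libraries, with known changes. Of 12943 genes in that step, the test recovered 50 of 67 genes changed by 0.5 on the log2 scale (74.6%), 61 of 67 changed by 1 (91.0%) and 66 of 66 changed by 2, with 7 calls among 12744 unchanged genes. The list that was shifted ranked 1, and 0 of 42 unshifted lists were called. Genes were drawn independently and lists were filled at random, so this step cannot show how camera behaves when genes are correlated. The spread of each gene was set to its trend with expression level. Far fewer genes were changed than were called in the libraries themselves.

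Alternatives fixed before the data were examined were the size factors of DESeq2, upper quartile scaling, library size alone, no filter, a filter of 5 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate block, removal of mitochondrially encoded genes, and removal of each library in turn. A likelihood ratio test with a preset biological coefficient of variation of 0.1, 0.2 or 0.4 was added after seeing the data. Splits of the samples into other groups were not counted, since each group has 2 libraries. Figures were drawn with matplotlib.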

Results

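Gene expression was measured by RNA-seq in MCF10AT, a human mammary epithelial line of the MCF10A lineage transformed by an oncogenic form of HRAS. The 4 libraries fell into 2 groups of 2 replicates, a genotype labelled Bromo+/- and a non-target control, and the labels do not spell out the first name further. The libraries labelled Bromo+/- held 11975396 and 10953756 counts over all genes, and the control libraries held 10835237 and 11884715. Of the 58233 genes listed, 13179 had enough counts to be tested. Mitochondrially encoded genes took 5.05% and 5.18% of the counts in the libraries labelled Bromo+/- and 4.32% and 4.21% in the controls. Values below are scaled CPM (counts relative to library size), given as mean ± SD (n = 2 per group), and log2 fold changes of the libraries labelled Bromo+/- over control, with their standard error (SE). Floors and counting intervals cover counting error only.

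The series as a whole concerns EP300, the gene of the acetyltransferase p300, and its title speaks of lowered EP300. EP300 lies on chromosome 22 (GRCh38, 41091786 to 41180079). EP300 was not lower in the libraries labelled Bromo+/-: it stood at 124 ± 3.73 CPM there and at 109 ± 3.16 CPM in the controls, a log2 fold change of 0.19 (SE 0.06, adjusted p = 0.00701, edgeR quasi-likelihood test). That call ended with the DESeq2 Wald test (adjusted p = 0.0639) and without control replicate 1 (adjusted p = 0.162, edgeR), and over all alternatives that estimate the spread from the libraries the adjusted p lay between 0.000105 and 0.162. CREBBP, the paralogue of EP300, rose to 104 ± 3.67 from 79.1 ± 5.22 CPM (log2 fold change 0.39, SE 0.07). Gene-level counts do not resolve single exons, so they cannot show whether a bromodomain is altered on one allele, and the direction of every change below rests on the group labels. Of 13 tested genes of the list of p300/CBP and other histone acetyltransferases, 7 rose, among them KAT2B (log2 fold change 1.00) and NCOA1 (0.66), 1 fell (KAT8, -0.22) and 5 did not pass. Of 28 tested bromodomain proteins 9 rose, led by ZMYND8 (0.71), BRD3 (0.78) and BRPF3 (0.74), 2 fell and 17 did not pass. Over all tested genes 53.5% passed the threshold. Neither list moved against the other genes by camera (adjusted p = 0.106 and 0.0945). By fry, which does not compare a list with other genes, the acetyltransferase list was higher (adjusted p = 0.0209). The bromodomain list was not called by fry (adjusted p = 0.103).

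The largest and most uniform difference between the groups was in genes of epithelial cells. CDH1, which encodes E-cadherin, the adhesion receptor of epithelial junctions, stood at 2.54 ± 0.09 CPM in the libraries labelled Bromo+/- and at 411 ± 7.72 CPM in the controls (chromosome 16, 68737225 to 68835548; log2 fold change -7.33, SE 0.18). CLDN7, a tight-junction claudin, fell to 3.53 ± 0.27 from 247 ± 2.51 CPM, EPCAM, an epithelial adhesion molecule, fell to 13.1 ± 0.49 from 293 ± 2.42 CPM, and ESRP1, a splicing factor of epithelial cells, fell to 0.721 ± 0.02 from 185 ± 9.13 CPM. All 28 tested epithelial junction genes were lower past the threshold, with a median log2 fold change of -4.21. S100A14, a calcium-binding protein of epithelia, had the smallest p among the lowered genes and fell to 8.08 ± 0.35 from 1459.8 ± 38.2 CPM (log2 fold change -7.50, SE 0.11).

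Markers of both mammary epithelial layers were lower. Of 21 tested basal markers 18 fell, 2 rose (MME and MYLK, the call for MYLK ending with the DESeq2 Wald test and without replicate 1 of either group) and NGFR did not pass (median log2 fold change -2.32). The fall took in the stress keratins KRT6B (log2 fold change -7.90) and KRT6A (-4.02), near-identical genes whose counts may be split between them, the desmosomal cadherin DSG3 (-5.72) and P-cadherin, CDH3 (-3.95). Of 16 tested luminal markers 13 fell and 3 rose, CA12 and ERBB2 among them, with a median of -2.26. KRT8 (-2.98) and KRT18 (-2.25) fell, as did the surface protein CD24 (-3.82). KRT8 and KRT18 overlap in the annotation, which leaves their separate levels uncertain. Among 20 tested genes of squamous differentiation and cornification 16 fell, 3 rose (KRT80, FLG and TGM2) and CNFN did not pass. The median was -5.27 as fitted and -4.49 with the 4 genes that had no count in one group set at their bound. The skin proteases KLK7 (4 counts against 5533) and KLK5 (5 against 2474) fell by 10.44 and 8.97 on the log2 scale. SPRR2D, a cornified envelope precursor with close paralogues, had 1 count against 956, a ratio of control to Bromo+/- of 1022 (95% exact interval 183 to 40412).

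**Figure D1:**
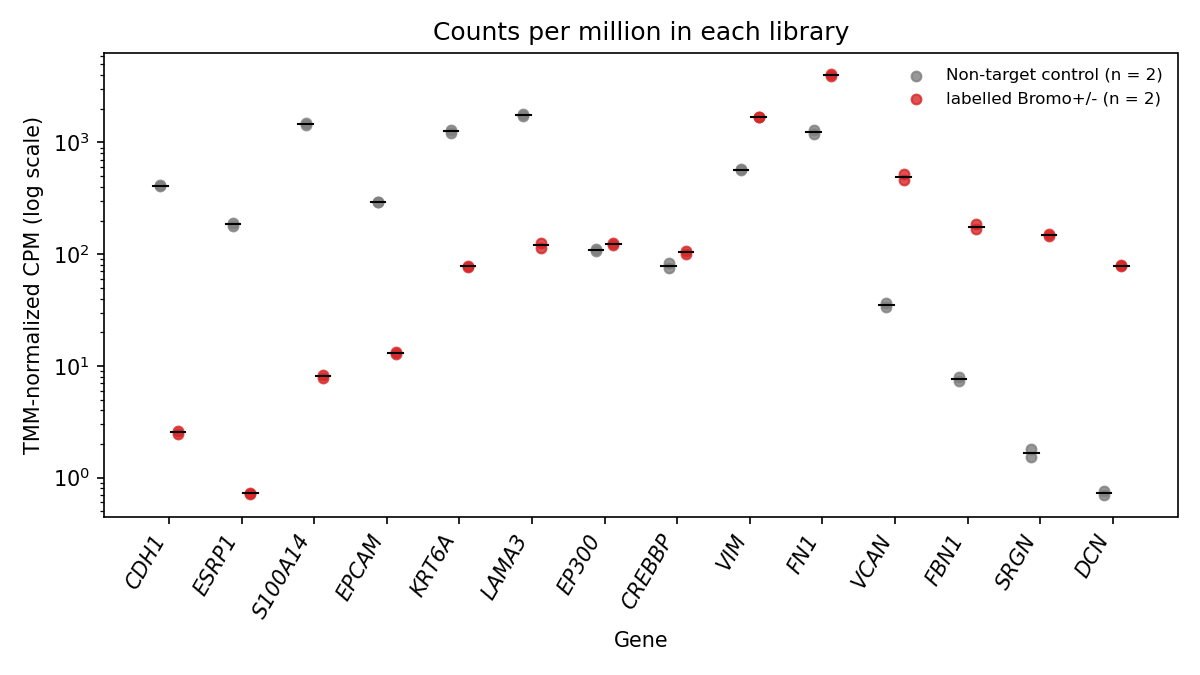
Scaled CPM (log axis) of 14 genes in each library, with grey points for the 2 control libraries, red points for the 2 libraries labelled Bromo+/- and a short line at each group mean. CDH1 lies at 411 CPM in the controls and 2.54 CPM in the libraries labelled Bromo+/-, DCN at 0.728 and 79.1 CPM, and EP300 at 109 and 124 CPM.

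Genes of mesenchymal cells and of the matrix they secrete were mostly higher. FN1, which encodes fibronectin, rose to 4011 ± 118 from 1242 ± 71.0 CPM (log2 fold change 1.69, SE 0.05), and the intermediate filament gene VIM rose to 1699 ± 5.43 from 569 ± 7.77 CPM (1.58, SE 0.05). POSTN, which encodes the matrix protein periostin, rose by 7.56 on the log2 scale (SE 0.72), from 4 counts in the controls to 853. Of 24 tested mesenchymal genes 17 rose, 2 fell (MMP14 and TNC) and 5 did not pass (SNAI1, SNAI2, TWIST1, S100A4 and TAGLN), with a median of 1.23. In the list of collagens and laminins 17 of 25 tested genes rose and 6 fell, with a median of 0.64. Members with small p went the other way: LAMA3 (-3.87) and LAMB3 (-2.97), laminin chains of the epithelial basement membrane, and COL17A1 (-5.08), a hemidesmosome collagen, all fell. Of 24 tested TGF-beta and SMAD targets 14 rose, among them CCN2 (2.85) and TGFB1 (1.98; its exons overlap HNRNPUL1), and 6 fell, led by INHBA (-3.31). Of 5 tested fibroblast markers DCN (6.75), POSTN, FBLN1 (1.43) and COL1A1 (1.38) rose and FAP fell (-1.19).

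The rises named for their size or small p ran from genes without any control count to abundant matrix genes. CACNG8, a subunit of neuronal channels, had 493 counts in the libraries labelled Bromo+/- and 0 in the controls, at least 154-fold higher against a floor of 3 counts over the group. MYEF2 was at least 69.2-fold and the pseudogene TPTEP1 at least 55.8-fold higher on the same floor. RTN1, a reticulon, had 1615 counts against 2, a ratio of 755 (95% exact interval 209 to 6242), SULF1, a heparan sulfate sulfatase, had 206 against 1, a ratio of 193 (34.2 to 7647), and ANKRD1 had 506 against 3, a ratio of 158 (53.7 to 768). The fibrillin genes FBN2 (log2 fold change 6.92, SE 0.28) and FBN1 (4.52, SE 0.12), the proteoglycan genes DCN (6.75, SE 0.36), SRGN (6.45, SE 0.24) and VCAN (3.81, SE 0.07), and the protease inhibitor SERPINE2 (2.99, SE 0.05) were also among the named rises. At the other end, A2ML1, a protease inhibitor of stratified epithelia, had 1 count against 2801, a ratio of control to Bromo+/- of 2995 (537 to 118323). No count was found in either library labelled Bromo+/- for KLK10, SPRR2A, ANKRD22, BICDL2, CAPN8, GUCY1A1, TMPRSS13 and MUC16. These were at least 194-fold (KLK10), 115-fold (SPRR2A), 113-fold (ANKRD22), 90.5-fold (BICDL2), 83.4-fold (CAPN8), 81.3-fold (GUCY1A1), 77.3-fold (TMPRSS13) and 75.9-fold (MUC16) lower.

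Inflammatory and sterol genes were lower as well. None of 26 tested NF-kB targets, cytokines and chemokines rose and 19 fell, with a median of -1.20, among them the acute-phase gene SAA1 (log2 fold change -3.62), the feedback inhibitor TNFAIP3 (-2.70), BIRC3 (-1.84) and the cytokine LIF (-1.61). Of 23 tested genes of cholesterol biosynthesis and its control 20 fell, 2 rose (PMVK and TM7SF2) and CYP51A1 did not pass, with a median of -0.91. The fall included HMGCS1 (-2.20), MSMO1 (-1.58), FDFT1 (-1.20) and SQLE (-1.07), enzymes along the pathway. In the list of MHC class I presentation 9 of 15 tested genes fell, among them the peptide transporters TAP2 (-0.94) and TAP1 (-0.58), and 2 rose. Counts of the HLA genes in this list are uncertain because these genes share sequence. Of 27 tested type I interferon genes 11 fell, led by SAMD9 (-1.71) and the RNA sensors RIGI (-1.62) and IFIH1 (-2.27), and 5 rose, led by IFI44L (2.98). The other 11 did not pass, and camera did not call the interferon list (adjusted p = 0.13).

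Targets of p53 and of NRF2 were mostly higher. Of 26 tested p53 targets 22 rose, 3 fell (PLK3, PHLDA3 and GADD45A) and AEN did not pass, with a median of 0.51. TP53INP1 rose to 17.7 ± 1.58 from 4.04 ± 1.18 CPM, and EDA2R (log2 fold change 1.27), RRM2B (0.82) and FDXR (0.99) rose too. Of 21 tested NRF2 targets and aldo-keto reductases 15 rose, 1 fell (the transporter ABCC2, -1.10) and 5 did not pass, with a median of 0.49. HMOX1, the heme oxygenase, rose to 113 ± 11.4 from 20.1 ± 0.64 CPM, and NQO1 rose by 0.93 and AKR1C2, whose close paralogues make its count uncertain, by 1.73 on the log2 scale. Of 14 tested replication-dependent histone genes 7 rose, led by H2BC21 (1.75), and none fell. Histone transcripts are mostly without a poly(A) tail and alike in sequence, so a poly(A)-selecting kit samples them poorly.

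Several signalling lists leaned lower with members on both sides. These counts describe transcript levels, and pathway activity was not measured. Of 26 tested genes of RAS-MAPK output 15 fell, including the EGF-family ligands HBEGF (-4.64) and TGFA (-1.27), UPP1 (-2.45) and FOS (-2.41), and 8 rose. Of 13 tested WNT genes 8 fell, among them SFRP1 (-3.10), WNT7B (-3.55) and RNF43 (-2.77), while WNT5A rose from 5 counts to 316 (5.82) and DKK1 rose. Of 14 tested NOTCH pathway genes 10 fell, led by MFNG (-4.54), NOTCH3 (-1.44), DTX4 (-1.02) and HES1 (-1.14), and MAML1 rose. Of 26 tested homeobox and developmental regulators 16 fell, among them RUNX1 (-0.89) and TFAP2A (-0.90), and 6 rose, with TBX3 at 1.80. Among 11 tested genes of stemness and drug resistance 7 fell and 3 rose, with ALDH3A1 at 3.64. The falls included CD24 (-3.82), which is also counted among the luminal markers, and ALDH1A3 (-2.54). Falls in the lists of heat shock proteins (7 of 14 tested, led by HSPB1 at -0.59) and of MYC and ribosome biogenesis (15 of 28 tested, with MYC at -0.37) were small.

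Lists that camera did not call mostly had members on both sides. Of 35 tested mitotic genes 16 fell, led by ANLN (-0.87), and 4 rose, with TOP2A at 0.27, and of 37 tested replication genes 10 fell and 4 rose, with TYMS at 0.80. Of 46 tested cytosolic ribosomal protein genes 37 did not pass, and of 35 tested nuclear-encoded genes of oxidative phosphorylation 28 did not. Of 13 tested mitochondrially encoded transcripts 6 rose, with MT-ND1 at 0.72, and 2 fell. Hypoxia targets split 7 higher and 7 lower of 24 tested, with LOXL2 (1.99) and STC2 (1.45) rising and the glucose transporter SLC2A1 (-1.09) falling. Of 17 tested glycolytic genes 8 rose, with ENO2 at 2.64, and 2 fell. Of 21 tested genes of fatty acid synthesis and lipid metabolism 10 fell, led by the desaturase SCD (-1.19), and 6 rose. YAP and TEAD targets split 9 higher and 7 lower of 21 tested, with CCN2, ANKRD1 and CCN1 (1.15) rising. Of 17 tested glucocorticoid response genes 10 rose, with DUSP1 at 2.49, and 3 fell. Of 26 tested genes of the unfolded protein response 12 fell, with TRIB3 at -1.35, and 6 rose. Of 18 tested genes of angiogenesis and secreted proteases 10 fell, with SERPINB2 at -8.37, and 5 rose, with TIMP1 at 2.05. Apoptosis regulators split 6 higher and 9 lower of 21 tested, with BIK at -3.79. Histone deacetylases and sirtuins had 8 higher and 4 lower of 16 tested, and their median (0.09) and mean (-0.04) differ in sign because HDAC9 fell by 2.20.

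Markers of other cells and of RNA handling were read beside these groups. Of 4 tested leukocyte markers 3 fell (CORO1A, CSF1R and CD14), of 4 tested endothelial markers EGFL7 and KDR rose and ROBO4 fell, with a median of 0.01 and a mean of -0.04, and of 6 tested myoepithelial and smooth muscle markers 2 rose and 2 fell. The 2 lists for leukocytes and endothelium were too short for camera. Calls for CD14 and KDR ended with the DESeq2 Wald test, for CD14 also without control replicate 1, for KDR without replicate 2 of either group, and for EGFL7 without Bromo+/- replicate 1. Of 20 tested immediate early and stress genes 12 fell, with FOS at -2.41, and 5 rose, with DUSP1 at 2.49. Of 6 tested nuclear-retained and short non-coding RNAs MALAT1 (0.59), NEAT1 (0.32) and GAS5 (0.20) rose, GAS5 no longer past the threshold without control replicate 2.

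**Figure D2:**
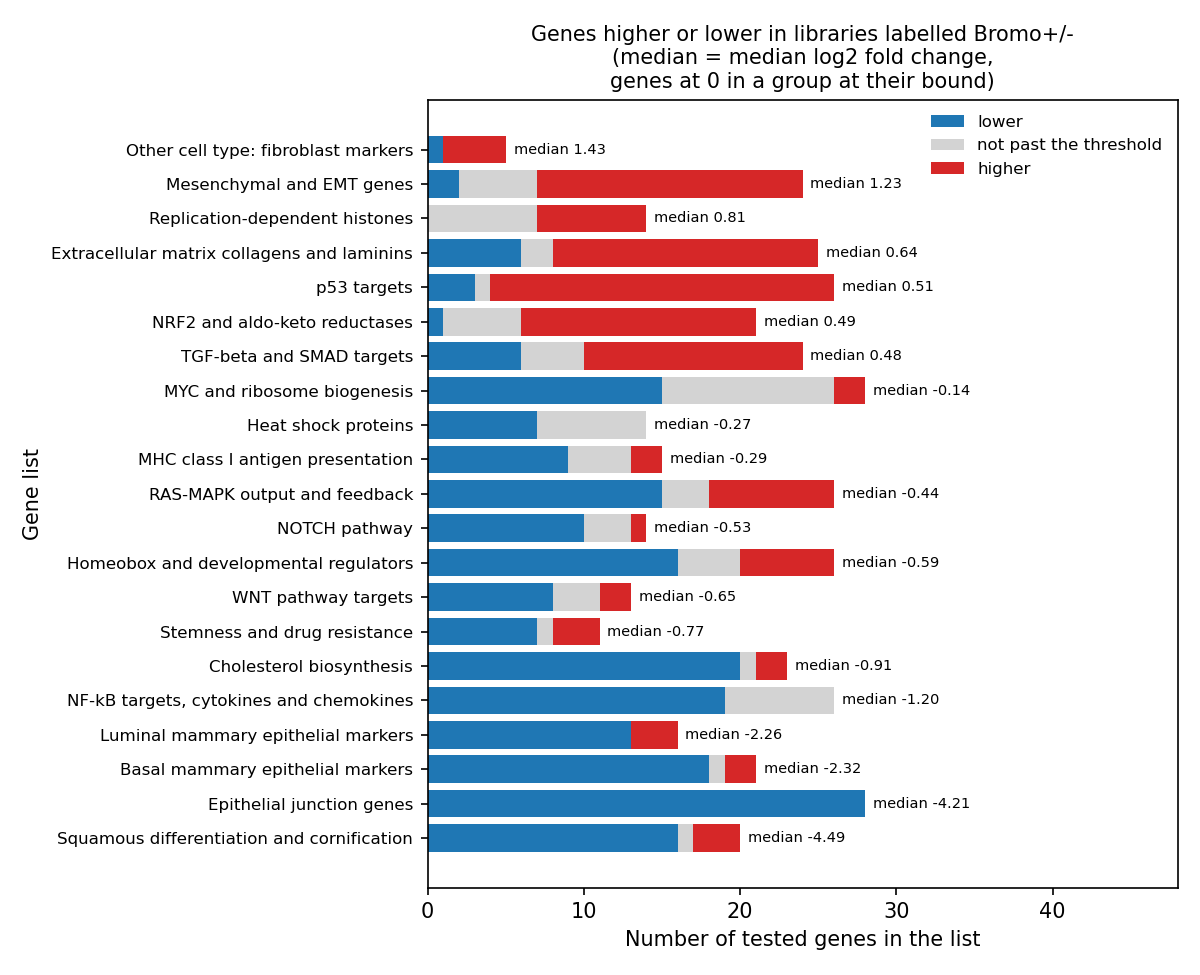
Number of tested genes (horizontal axis) that were lower (blue), higher (red) or not past the threshold (grey) in the libraries labelled Bromo+/- for each of the 21 gene lists that camera called with a preset correlation (none with an estimated one), ordered by median log2 fold change, with genes at 0 counts in a group set at their bound. All 28 epithelial junction genes are lower (median -4.21), and 17 of 24 mesenchymal genes are higher (median 1.23).

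Across all genes, 7055 of 13179 (53.5%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3485 higher and 3570 lower, against 7655 at an unadjusted p under 0.05. A difference of 2-fold or more was reached by 1973 of them, 980 higher and 993 lower. Changes of 16-fold or more were more often losses, 201 against 74 gains. Both libraries of a group lay on the same side of both libraries of the other for 9916 genes (75.2%), against 33.3% by chance. Scaling by library size alone gave 4433 higher and 2794 lower, since it shifts the median of the log2 fold changes by 0.08. With 2 libraries per group, and no label saying that they came from separate cultures or clones, these p-values measure only the spread between these samples, which may be technical. The column names share an unexplained number within each group, so both libraries of a group may come from a single clone.

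Of 43 gene lists fixed before the data were examined, 41 had the 5 tested members that camera needed. With a preset correlation of 0.01 between genes, camera called 7 higher and 14 lower. None of these 21 calls held with a correlation estimated per list, where the lowest adjusted p was 0.292, with 2 libraries per group to estimate it from. With the preset correlation, the adjusted p was 7.48e-18 for epithelial junction genes, 1.07e-08 for basal markers, 3.85e-07 for NF-kB targets, 5.89e-07 for cholesterol genes, 1.25e-06 for squamous genes, 4.62e-05 for p53 targets, 0.00012 for mesenchymal genes, 0.000219 for luminal markers, 0.000453 for histones and 0.000703 for NRF2 targets. For the other 11 lists called, the adjusted p by camera lay between 0.0265 for collagens and laminins and 0.0461 for RAS-MAPK, WNT and MYC genes. Of these 11 lists, stemness and drug resistance kept its call under every alternative to the normalization, filter, test, block and libraries, and the other 10 lost it under at least 1. The histone call ended without the filter on low counts (adjusted p = 0.0651, camera). Adjusted over the list alone, the counts above were unchanged for most lists and moved by at most 1 gene per direction for those called by camera: cholesterol genes had 21 lower, RAS-MAPK genes 16 lower, TGF-beta targets 15 higher, NOTCH genes 2 higher and collagens and laminins 7 lower.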

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

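The tests with a preset biological coefficient of variation were chosen after the data were seen. Of 212 named genes, 191 kept direction and call under every alternative fixed beforehand, and of 21 called lists 10 did, leaving aside the estimated correlation. Of 7055 calls, 4884 were shared with the DESeq2 Wald test, all in the same direction, and its count of higher genes was 2292 against 3485. The filter of 5 CPM left fewer genes to test (10621) and 1214 calls of 2-fold or more against 1973. The EP300 difference missed the threshold with the DESeq2 Wald test (log2 fold change 0.18), and it lay between 0.15 and 0.22 when single libraries were left out. With a preset biological coefficient of variation of 0.1, 4234 genes passed (2146 higher, 2088 lower) and EP300 did not (0.19). At 0.2, 2144 passed (1027 higher, 1117 lower) and EP300 did not (0.19). At 0.4, 890 passed (359 higher, 531 lower), all changed 2-fold or more, and EP300 did not (0.19). Leaving out single libraries gave 5551 to 6641 calls. The replicate block gave 7271 calls, 6985 of them shared. Same-numbered libraries deviated together with a correlation of only 0.05 across genes. The counts thus hold little shared effect of the replicate number, but cannot show whether same-numbered libraries were handled together. With library size alone camera called 4 lists higher against 7. With an estimated correlation it called 0 higher and 0 lower, and fry, which does not compare a list with other genes, called 14 higher and 20 lower. The DESeq2 Wald test was run for genes and for counts per list, not for camera, which does not use it. The lists that turned direction were not called by camera, though fry called hypoxia targets higher, and the genes that turned did not pass the threshold. The camera direction turned for ribosomal proteins with upper quartile scaling (median 0.047), with library size alone (0.072) and without Bromo+/- replicate 2 (0.044), and their median ranged from -0.074 to 0.044 without single libraries. Without the filter on low counts the camera direction turned for hypoxia targets, though their median stayed above 0 (0.064 against 0.097 in the main test). It also turned for myoepithelial markers (median 0.15 against -0.16). CD8A turned with library size alone (0.019), without control replicate 1 (0.26) and, at a value near 0, without Bromo+/- replicate 2, and ranged from -0.36 to 0.26 without single libraries. RN7SL2 turned without control replicate 2 (0.012) and ranged from -0.56 to 0.012. The causes were not tested. At this depth 1 to 3 counts in a group leave ratios with wide intervals, as for RTN1.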

Other observations

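The tests weighed below were chosen after the results were seen, except the comparison of neighbouring pairs with shuffled orders and that of pairs whose symbols differ in their starting letters, both written before their values were computed. Within the mesenchymal list some regulators rose and others did not pass, an observation made after their values were seen. No test compared these regulators with each other. ZEB1 rose to 27.2 ± 1.42 from 2.74 ± 0.45 CPM (log2 fold change 3.31, SE 0.20) and ZEB2 to 30.4 ± 1.67 from 1.91 ± 0.01 CPM (3.99, SE 0.24); both encode repressors of epithelial genes. SNAI1 (-0.44, SE 0.23), SNAI2 (-0.12, SE 0.09) and TWIST1 (0.12, SE 0.13) did not pass, and TWIST2 was higher by 0.51 on the log2 scale, a call that ended with the DESeq2 Wald test. Some transcription factors expressed in epithelia, picked after their values were seen and not tested as a group, were lower: GRHL2 fell to 1.32 ± 0.26 from 64.2 ± 4.64 CPM, TP63 fell to 0.344 ± 0.14 from 22.5 ± 0.28 CPM, ELF3 by 7.90 and OVOL2 by 5.33 on the log2 scale, and OVOL1, with 0 counts against 140, was at least 49.9-fold lower. MIR205HG, the host transcript of an epithelial microRNA, had 9 counts against 1688. MGMT, which encodes a DNA repair enzyme, had 0 counts against 184, at least 65.6-fold lower. HRAS itself was higher, at 228 ± 10.7 against 158 ± 3.83 CPM (log2 fold change 0.53, SE 0.06).

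Some gene families leaned one way and others did not; they were chosen after the data were seen, and no test was run across families. Of 20 tested keratins 19 fell and KRT80 rose (0.24). Claudins had 6 lower of 7 tested, kallikrein-related peptidases 5 lower of 6, transmembrane serine proteases 7 lower and 1 higher of 10, and desmogleins, desmocollins and plakophilins 7 lower of 7. Of 9 tested fibrillins, fibulins and latent TGF-beta binding proteins 8 rose, with LTBP3 not past the threshold (0.16), and all 5 tested insulin-like growth factor binding proteins rose, with a median log2 fold change of 2.37 and IGFBP4 at 3.91. The scaling alternatives shift log2 fold changes by at most 0.08 in the median, which turns no direction named here; LTBP3 passed the threshold with upper quartile scaling (0.22) and with library size alone (0.24), and also with the filter of 5 CPM, with the replicate block and without Bromo+/- replicate 2. Integrin chains split, with 7 higher and 5 lower of 16 tested, as did semaphorins and plexins (10 higher and 10 lower of 23), ADAMTS proteases (2 higher and 2 lower of 6), clustered protocadherins (2 higher and 1 lower of 5), schlafens (3 higher and 1 lower of 5) and S100 proteins (2 higher and 7 lower of 12).

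The first pattern is the near-complete loss of epithelial transcripts beside the rise of matrix transcripts. A gain or loss of whole chromosomes is argued against, since the chromosome whose median log2 fold change lay farthest from that of all genes, chromosome 18, differed by -0.081 (bootstrap SE 0.025). Stromal cells in the libraries labelled Bromo+/- cannot be told apart from a change in the cells themselves by the list of fibroblast markers: 8 of its 13 members, COL1A2 and COL3A1 among them, stayed under 1 CPM in both libraries, although the level of CDH1 would need nearly all RNA to come from such cells, while DCN, POSTN, FBLN1 and COL1A1 rose and FAP fell. This test on the whole list took the place of one on members picked after their counts were seen. Another clone, or another line of the same origin, cannot be told apart from an effect of the genotype: 3 of 3 genes at 9p21 (CDKN2A, CDKN2B and CDKN2B-AS1) had 0 counts in all 4 libraries, as a shared origin would give, and each group may stem from a single clone. An effect of the genotype in the labels stays open as the biological hypothesis, untested by a second clone or a rescue.

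The second pattern is that genes lowered 16-fold or more lie next to each other along the chromosomes. Among tested genes, 201 such genes formed 32 neighbouring pairs, against a mean of 3.06 in 10000 shuffled orders (p = 0.0001, the smallest these shuffles can give, one-sided permutation test), while 74 genes raised 16-fold or more formed 2 pairs (p = 0.06). Families side by side, such as KLK5 to KLK10 or the SPRR genes, are not the whole account, since 15 pairs had symbols that differ in the letters before their first digit or other sign, against a mean of 3.04 in shuffled orders. The 15 include related pairs such as DSC2 with DSG3; by the first letter alone, counted after the result was seen, 13 pairs differed, against a mean of 2.92 in shuffled orders (p = 0.0001, one-sided permutation test). Overlapping genes together with families cannot be told apart from some further cause: among protein-coding genes, 6 pairs that did not overlap and differed in their first 3 characters remained, against a mean of 2.38 in shuffled orders and an upper end of their central 95% of 6 (p = 0.03, one-sided permutation test), too few pairs to decide, and pairs such as DSC2 with DSG3 and IL37 with IL1RN are still related. This test took the place of chance order as an explanation after chance order had failed, and the rule for reading it was set, and later changed, after its value was seen. Loss of the DNA that holds these genes cannot be told apart from silencing for most of them. Of the 54 genes in such pairs 16.7%, CDH1 with 60 counts among them, had 10 or more counts in the libraries labelled Bromo+/-. The rest had too few to decide. The selection itself limits this share: a gene with few control counts, such as KLK8 with 28, could not keep 10 after a 16-fold fall.

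The third pattern is that EP300 was not lower where the series title would have it lower. The choice of scaling cannot be told apart from a true rise: the lowest log2 fold change over the 3 other scalings was 0.18, but none of them lowers the median of all genes by enough to have brought EP300 under 0. An exchange of the group labels cannot be told apart from a genotype that leaves the amount of EP300 transcript as it is. With exchanged labels the libraries labelled control would be the edited ones, and the difference of 0.19 would be a decrease in them. The libraries labelled control hold the epithelial transcripts expected of a mammary epithelial line (CDH1 at 411 against 2.54 CPM, EPCAM at 293 against 13.1 CPM), which runs the way the labels say, but no library of untreated cells was there to compare, and gene-level counts hold no other mark of the edit.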
